A study of Mus musculus with 48 samples.

How the data were processed

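The series holds 48 arrays from 24 FvB/NJ mice. From each mouse, cortex and striatum were hybridised separately to Illumina MouseRef-8 bead arrays, a 1-colour platform with 1 biotin-labelled sample per array. The mice were wild-type or BACHD-ΔN17, which carry mutant human huntingtin on a bacterial artificial chromosome in a version without its N-terminal amino acids, and were aged 2, 7 or 11 months. Each of the 12 groups (region, genotype and age) had 4 mice, 2 males and 2 females. Groups, ages, sexes and replicate numbers were taken from the sample labels.

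Per the labels' protocols, tissue was disrupted in Trizol, RNA was purified on Qiagen RNeasy columns with DNase digestion, and 100 ng of total RNA was amplified and biotin-labelled with the Ambion TotalPrep kit. The authors deposited a table with the summarised bead intensity of each probe on each array, on a linear scale and not normalized. Beside each intensity the deposited table gives a detection p-value, the chance of a signal that high from negative control beads. The scanner software and version are not given in the sources. A second deposited table holds the authors' processed values on a log2 scale. Set against the intensities, these log2 values were the log2 intensities after quantile normalization without background correction: sorted values differed by at most 0.00194, every column had the same median of 7.9435, and each of the 48 columns correlated best with its own sample (lowest r = 0.9993, across probes). Their scale, centring and direction are therefore known from this comparison, not from the authors.

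The intensities were background-corrected and quantile-normalized over all 48 arrays with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, with an offset of 16. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none. These stood for 16593 named genes, 4777 of them with more than 1 probe, and the probe with the highest mean over the 48 arrays was used for each gene, with unnamed probes kept as they were. This left 18312 features. A lookup in the mouse reference gene table changed 0 symbols. A feature was tested in a region if its detection p was under 0.05 on at least 4 arrays of that region, which left 11225 features in striatum, 11047 in cortex and 11573 for the differences between regions.

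For each region, a limma model with the 6 group means and sex was fitted to the 24 arrays, with moderated variances that follow the mean intensity (eBayes with a trend). From it came the genotype difference at each age, its mean over the ages, its change from 2 to 11 months, and the age difference in wild-type mice. Comparisons between regions used the within-mouse difference of striatum minus cortex in the 24 mice. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. All log2 differences are BACHD-ΔN17 minus wild-type unless stated, and every adjusted p for a gene comes from limma. Lists of marker genes and pathways were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. A list count adjusted over the list alone is given beside the count over all genes.

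The comparisons, tests, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest increases and decreases of each genotype comparison, up to 10 called members of each list, and the 6 largest changes each way in the other comparisons. It also takes Htt, sex-linked genes and a set of striatal genes whatever their values. The text names at most the first of these by size, 6 each way and 2 per list (3 each way in the other comparisons). That narrowing was made for length after the values were seen. The counts of results that change with the processing cover every gene the rule takes. Penk, Adora2a and Ddx3y had no probe with that name, and Eif2s3y was not detected. A gene undetected on all arrays of 1 group has only a bound there. Its fold is written as "at least", from the brighter group's mean against the mean, per array, of the higher of the detection floor and the probe's own value, and its fitted log2 difference is given only beside that bound. A group detected on 1 or 2 arrays lies near the floor, so the size of its difference is uncertain. The detection floor was 5.62 to 6.17 on the normalized log2 scale.

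Simulated tests used real means and spreads. Without changes 0 genes were called, but a wrong split of 2-month striata gave 195. Of the genes changed by 0.5, 1 and 2 on the log2 scale, 46.3%, 80.6% and 100% were called for a genotype difference at 11 months in striatum, 46.3%, 83.6% and 98.5% in cortex, and 22.4%, 73.1% and 100% for the difference between regions. Wrong calls were 3.82%, 3.18% and 5.11% of all calls.

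Each array detected 12477 to 14378 probes (median 13630). The highest correlation between any 2 arrays was 0.99539, and no 2 arrays held identical values. The labels give an internal sample number from 1 to 48. Its consecutive eights were treated as possible chips, since no label names the chips. Numbers 1 to 8 were dim: their 95th percentile of intensity was 2556 to 3082, against 3746 to 5806 on the other arrays. Among residuals from the group means, the first principal component (19.5% of the variance in striatum, 26.2% in cortex) separated numbers 33 to 48 from numbers 1 to 32. After seeing this, 5 alternatives were added: the eights as a fixed factor, these sets of arrays as a fixed factor, only numbers 1 to 32, only numbers 33 to 48 (cortex only) and no dim arrays. The alternatives chosen beforehand concerned background correction, normalization, the authors' values, arrays normalized together, detection filter, probes per gene, sex, groups in the fit, blocks, array weights, the variance trend, the threshold and leaving out each mouse. Mice are named by group and replicate number within a region, and 1 number can mean different mice in cortex and striatum. Arrays of a mouse were matched by its name in the labels.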

Results

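Transcript levels were measured in cortex and striatum of wild-type and BACHD-ΔN17 mice at 2, 7 and 11 months of age, with 4 mice per group and both regions from the same mice. BACHD mice are a model of Huntington's disease, and ΔN17 marks the loss of the N-terminal segment of the mutant huntingtin they express. Array brightness was uneven: the 8 arrays with the lowest internal sample numbers were dim, and they held 4 striatal arrays (a wild-type at 2 and at 7 months, a BACHD-ΔN17 at 2 and at 11 months) and 4 cortical arrays at 11 months (2 of each genotype). Counts and list medians are therefore also given with the consecutive eights of arrays or the sets of numbers 1 to 32 and 33 to 48 as a fixed factor, and within these sets where both genotypes had arrays. All BACHD-ΔN17 striatal arrays at 7 and 11 months were in numbers 1 to 32, so numbers 33 to 48 give no genotype difference there. In cortex numbers 33 to 48 held 2 wild-type mice at each age and 2, 1 and 1 BACHD-ΔN17 mice at 2, 7 and 11 months. Values from them at 7 and 11 months therefore rest on 1 BACHD-ΔN17 mouse, whose spread is taken from the other groups.

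Htt, the mouse gene of the protein whose human form the transgene encodes, did not pass the threshold in any comparison of genotypes. Its log2 differences (BACHD-ΔN17 minus wild-type) were 0.20, 0.11 and -0.10 in striatum at 2, 7 and 11 months and -0.03, 0.21 and 0.01 in cortex, with limma adjusted p from 0.812 to 1. The labels do not say whether the probe reads the human transcript, so this does not check the genotype labels. The sex labels were borne out on all 48 arrays: Xist, the RNA of the inactive X chromosome, lay at 8.97 to 10.3 (normalized log2) in females and 5.02 to 6.57 in males, and Kdm5d, a gene of the Y chromosome, at 4.73 to 5.48 in females and 6.35 to 7.73 in males. Uty, also on the Y chromosome, differed between genotypes by -0.38 to 0.35 over the 6 comparisons, which did not pass.

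**Figure D1:**
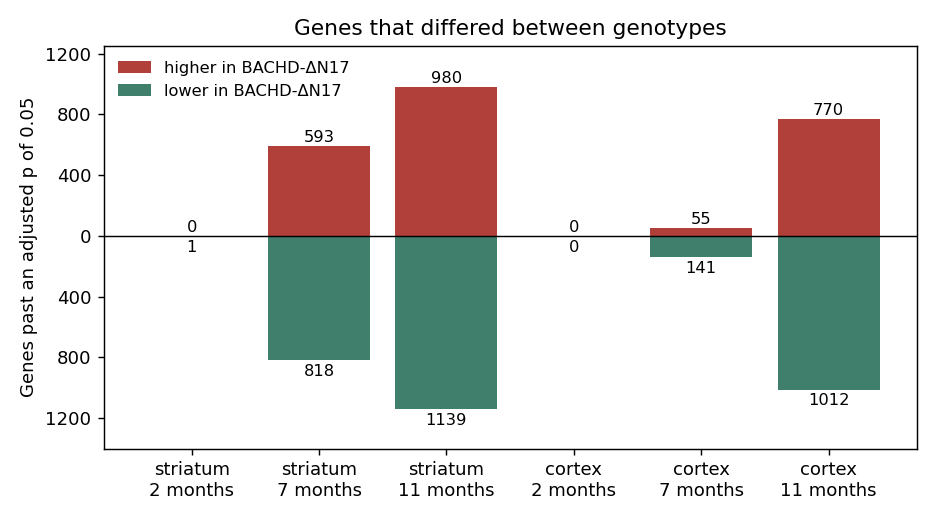
Number of genes past an adjusted p of 0.05 between genotypes (y axis), higher in BACHD-ΔN17 above the line and lower below it, for each region and age (x axis), 4 mice per group. Counts grew from 0 or 1 gene at 2 months to 2119 in striatum and 1782 in cortex at 11 months.

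In striatum at 11 months, transcripts of projection neurons, the inhibitory output cells of this region, were lower in BACHD-ΔN17 mice. Scn4b, a sodium channel beta subunit, stood at 12.32 ± 0.17 against 14.19 ± 0.05 in wild-type mice (normalized log2, mean ± SD, n = 4 each), a 3.66-fold difference. Log2 differences were -1.64 (SE 0.11) for Pde10a, the striatal phosphodiesterase, -2.03 (SE 0.19) for Cnr1, the cannabinoid receptor, -1.29 (SE 0.09) for Rgs4, a regulator of G protein signalling, and -0.67 (SE 0.08) for Ppp1r1b, the phosphoprotein of dopamine signalling. For the dopamine receptors Drd2 and Drd1 they were -1.65 (SE 0.13) and -1.12 (SE 0.08). The largest decreases over all genes were those of Ddit4l (-3.20, SE 0.15), an inhibitor of growth signalling, Ryr1 (-3.15, SE 0.22), a calcium release channel, Cyp2a5 (-2.95), a cytochrome P450, Ccno (-2.85), cyclin O, Egr2 (-2.57), an activity-dependent transcription factor, and Mas1 (-2.56), a receptor for angiotensin peptides. Of 3 other probes of Ryr1, 2 also fell (-2.97 and -2.10) and 1 gave -0.30 (adjusted p = 0.512). Bdnf, a neuronal growth factor, was undetected in BACHD-ΔN17 and detected in 1 wild-type striatum, at least 1.02-fold lower, and did not pass (fitted -0.30, adjusted p = 0.624).

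Of 31 tested members of the striatal projection neuron list, 27 fell and 0 rose (29 fell when adjusted over the list alone), with a median of -0.81. In the direct pathway list 4 of 8 fell (4 over the list alone), with Drd1 and Slc35d3 (-0.74), a transporter of these neurons, in front. In the indirect pathway list 3 of 7 fell (5), led by Upb1 (-2.27), an enzyme of pyrimidine breakdown, and Drd2. Glutamate receptor and postsynaptic genes (11 of 23 fell, 13 over the list alone) included the scaffold genes Homer1 (-1.02) and Shank3 (-0.98). Potassium channel genes (12 of 30 fell, 12) included Kcnip3 (-1.11) and Kcnq5 (-1.03, adjusted p = 0.0918 with the eights of arrays fixed), and calcium and cAMP signalling genes (20 of 36, 20) included Ryr1 and Pde10a. Interneuron genes (5 of 13, 5) included the acetylcholine handling genes Slc18a3 (-1.21) and Slc5a7 (-1.16), and immediate early genes (12 of 22, 13) included Egr2 and Npas4 (-2.34), a neuronal activity factor. No member of these lists rose. Of the GABA receptor genes 1 of 8 fell, Gabrd (-1.09, 1 over the list alone), and this list did not pass (camera adjusted p = 0.267). In the cortical excitatory neuron list 7 of 19 fell and 1 rose (7 and 2). Nptx1 (-1.0), a synaptic pentraxin, and Crym (-0.96), a thyroid hormone binding protein, fell most, but Crym is also in the projection neuron list. Cholesterol synthesis genes (6 of 18 fell, 6) included the sterol enzyme Msmo1 (-0.98) and the sterol sensor Insig1 (-0.67; other probes -0.65, adjusted p = 0.00031, and -0.51, adjusted p = 0.206). Slc35d3 lost its call without BACHD-ΔN17 mouse 1 or 3 or wild-type mouse 1 or 3 (log2 -0.65 to -0.67, adjusted p = 0.0595 to 0.0681), and without the dim arrays (adjusted p = 0.0707).

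Camera placed these lists, apart from the GABA receptor list, below other genes, with adjusted p from 5.27e-30 for projection neurons to 0.0249 for cortical excitatory neurons. The call was lost for 3 of them: adjusted p = 0.184 with an estimated correlation for immediate early genes, adjusted p = 0.114 with an estimated correlation for cholesterol synthesis and adjusted p = 0.267 with an estimated correlation for cortical excitatory neurons. With the eights as a fixed factor, the sets as a fixed factor and numbers 1 to 32 alone, medians were -0.86, -0.86 and -0.80 for projection neurons (all arrays -0.81), -0.36, -0.33 and -0.32 for the direct pathway (-0.35), -0.58, -0.65 and -0.60 for the indirect pathway (-0.50), -0.39, -0.36 and -0.35 for glutamate receptors (-0.40) and -0.24, -0.33 and -0.34 for potassium channels (-0.30). They were -0.46, -0.40 and -0.40 for calcium and cAMP signalling (-0.40), -0.38, -0.33 and -0.35 for interneurons (-0.39), -0.58, -0.67 and -0.65 for immediate early genes (-0.56), -0.20, -0.24 and -0.31 for cholesterol synthesis (-0.23) and -0.34, -0.16 and -0.12 for cortical excitatory neurons (-0.17). Without background correction the last pair had -0.14 and -0.11, and potassium channels -0.18. Under scale normalization medians grew to -0.68 for the direct pathway, -0.63 for glutamate receptors, -0.51 for potassium channels, -0.77 for calcium and cAMP signalling, -0.89 for immediate early genes, -0.42 for cholesterol synthesis and -0.43 for cortical excitatory neurons.

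**Figure D2:**
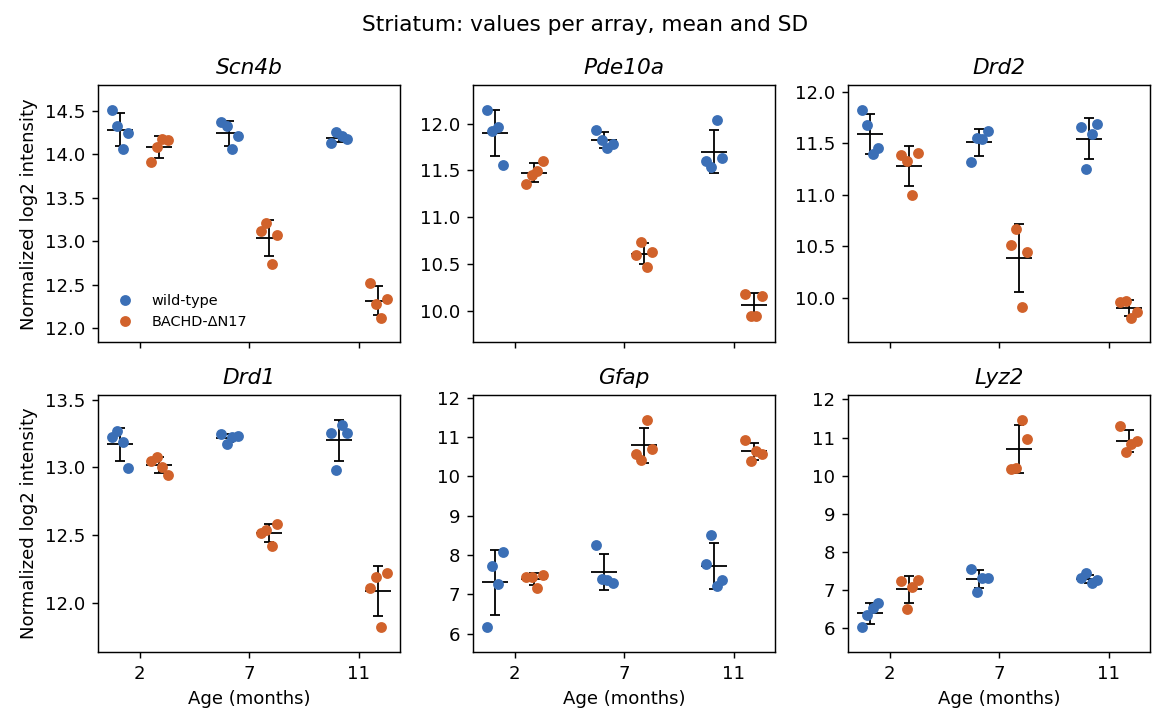
Normalized log2 intensity (y axis, scaled per gene) of 6 striatal genes by age in months (x axis). Each point is 1 mouse and bars give the mean and SD of 4 mice. At 11 months Scn4b lay at 12.12 to 12.52 in BACHD-ΔN17 and 14.13 to 14.25 in wild-type mice, and Gfap at 10.39 to 10.93 and 7.22 to 8.52.

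Reactive astrocyte and interferon response genes rose in the same striata at 11 months, and microglia genes moved both ways. Gfap, the intermediate filament of astrocytes, rose 7.54-fold (log2 2.91, SE 0.30), C4b, a complement component, 4.41-fold (2.14, SE 0.22), and the lysozyme genes Lyz2 and Lyz1 12.3-fold (3.62, SE 0.23) and 8.39-fold (3.07, SE 0.13). Plin4 (3.91, SE 0.58), of lipid droplets, Nrn1 (3.44, SE 0.51), of neurite growth, and Ch25h (3.05, SE 0.23), of oxysterols, also rose. Nrn1 was lower in wild-type striatum than cortex (-5.33). Wt1, a transcription factor of kidney and gonad development, was not detected in any wild-type striatum and was at least 6.56-fold higher (fitted log2 3.28, SE 0.21). Of 15 reactive astrocyte genes 10 rose and 0 fell (10 over the list alone), with a median of 0.87. Of 16 interferon response genes 9 rose and 0 fell (10). They were led by H2-T23, a class I histocompatibility gene (at least 1.63-fold, fitted 1.04), and Oasl2, an antiviral protein (1.00). Of 22 microglia genes 9 rose and 5 fell (10 and 5 over the list alone), with Lyz2 and Cd74 (1.82), the invariant chain of antigen presentation, rising most and the purinergic receptors P2ry13 (-1.01) and P2ry12 (-0.93) falling most. Of 17 astrocyte genes 2 rose, Gfap and Aqp4 (0.53), a water channel, and 1 fell (2 and 1). Of 7 homeobox cluster genes 2 rose (2 over the list alone): Hoxc6, undetected in wild-type mice (at least 3.76-fold, fitted 2.70), and Hoxb5 (0.87), both transcription factors of body axis patterning.

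Camera called the reactive astrocyte (adjusted p = 2.45e-09) and interferon lists (3.89e-05), both also with an estimated correlation, and not the microglia (0.0858), astrocyte (0.95) or homeobox lists (0.0702). The astrocyte list's median was -0.03 while its mean was 0.13, and the homeobox median of 0.18 was 0.08 with undetected members at their bounds. With the eights fixed, the sets fixed and numbers 1 to 32 alone, medians were 0.79, 0.89 and 0.85 for reactive astrocytes, 0.72, 0.55 and 0.59 for interferon response (all arrays 0.60) and 0.22, 0.17 and 0.18 for microglia (0.25). For homeobox genes they were 0.15, 0.14 and 0.18, and for astrocytes 0.01, -0.05 and -0.05. Without background correction they shrank to 0.31 for reactive astrocytes, 0.26 for interferon response, 0.10 for microglia and 0.04 for homeobox genes, and under scale normalization to 0.35 for interferon response and 0.14 for microglia. Scale normalization left 8 reactive astrocyte genes and 3 interferon genes higher, with 6 microglia genes higher and 5 lower, and the eights as a fixed factor 8 and 7 higher, with 7 microglia genes higher and 2 lower. Some calls rested on single mice. Cd74 lost its call without BACHD-ΔN17 mouse 1 (1.33, adjusted p = 0.0864) or 4 (1.56, 0.0553), H2-T23 without mouse 1 (0.69, 0.0618), and Oasl2 without BACHD-ΔN17 mouse 4 or wild-type mouse 3 or 4 (0.86 to 0.92, up to 0.0687). Aqp4 lost it without BACHD-ΔN17 mouse 1 (0.30, 0.242) or 4 or wild-type mouse 1, 3 or 4 (up to 0.109), and Hoxb5 without BACHD-ΔN17 mouse 2 or 3 or wild-type mouse 1, 2 or 4 (0.68 to 0.82, up to 0.136). On numbers 1 to 32 alone, Aqp4 (0.50, adjusted p = 0.0621) and Hoxb5 (0.80, 0.0815) did not pass. Without the dim arrays Cd74 (1.36, 0.079), H2-T23 (0.69, 0.064) and Aqp4 (0.30, 0.232) did not. With the eights fixed Hoxb5 (0.68, 0.147) did not, and neither did Aqp4 under scale normalization (0.22, 0.396) or Cd74 with another probe (1.60, 0.0621).

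Over all genes in striatum at 11 months, limma called 2119 of 11225, 980 higher and 1139 lower (46.2% higher). Counts were 1389 with the eights as a fixed factor, 2477 with the sets as a fixed factor and 1925 on numbers 1 to 32 alone. Scale normalization in place of quantile normalization called 1886, 265 higher and 1621 lower (14.1% higher), with the median of all genes moved to -0.168. The direction of small increases therefore depends on the scaling. Of the 65 called genes taken first by size, 15 lost their call when some mouse was left out.

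At 7 months the same kinds of transcripts differed in striatum. Scn4b stood at 13.04 ± 0.20 against 14.24 ± 0.14 (n = 4 each), a 2.30-fold decrease, Pde10a fell by 1.21 (SE 0.11), and log2 differences were -1.13 (SE 0.13) for Drd2, -0.70 (SE 0.08) for Drd1, -1.55 (SE 0.19) for Cnr1, -0.86 (SE 0.09) for Rgs4 and -0.46 (SE 0.08) for Ppp1r1b. Ppp1r1b did not pass under scale normalization (-0.64, adjusted p = 0.0883). Ddit4l (-2.44), Mas1 (-2.33), Cyp2a5 (-2.22), Ryr1 (-2.05), Tnfrsf25 (-2.0), a death receptor, and Il17rc (-1.94), an interleukin receptor subunit, had the largest decreases. Of 3 other probes of Ryr1, 2 also fell (-2.04 and -1.38) and 1 gave -0.15 (adjusted p = 0.787). Bdnf gave -0.65 (adjusted p = 0.234), and on numbers 1 to 32 alone -1.35 (adjusted p = 0.00713). Gfap rose 9.28-fold (3.21, SE 0.30), Lyz2 10.7-fold (3.41, SE 0.23) and Ch25h, detected in 2 wild-type mice, by 3.45 (SE 0.23). The chemokine gene Ccl4 was at least 10.9-fold higher (fitted 3.84) and Wt1 at least 6.94-fold (fitted 3.69), both undetected in wild-type mice, and Cd74 rose by 3.44 (SE 0.52).

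Of 31 projection neuron genes 24 fell and 0 rose at 7 months (27 over the list alone, median -0.58). Decreases without increases were also seen in the indirect pathway (3 of 7, 3 over the list alone, Upb1 -1.70), glutamate receptor (10 of 23, 12, Shank3 -0.99 and Homer1 -0.76), potassium channel (8 of 30, 12, Kcnj4 -0.86 and Kcnq5 -0.85), interneuron (3 of 13, 3, Slc18a3 -1.12 and Chat -0.97) and cortical excitatory lists (5 of 19, 6, Nptx1 -1.15 and Fezf2 -0.98). Calcium and cAMP genes fell in 16 of 36 cases and rose in 1 (19 and 1). Reactive astrocyte genes rose in 9 of 15 (11), with Gfap and C4b (1.53) in front, microglia genes in 11 of 22 with 1 lower (12 and 1), and interferon genes in 5 of 16 (8), led by H2-T23 (0.89) and B2m (0.83), the light chain of class I molecules. Chaperone genes rose in 5 of 22 (5), led by Ahsa2 (0.72) and Hspa4l (0.66). H2-T23 lost its call without any of the 8 mice but wild-type mouse 2 (0.80 to 0.91, adjusted p = 0.0657 to 0.106), and Fezf2 without BACHD-ΔN17 mouse 3 or 4 or wild-type mouse 2 or 4 (-0.79 to -0.90, 0.0895 to 0.154). Hspa4l lost it without BACHD-ΔN17 mouse 2, 3 or 4 or wild-type mouse 3 or 4 (0.55 to 0.70, 0.0672 to 0.128) and Kcnq5 without BACHD-ΔN17 mouse 3 or 4 (-0.78 and -0.76, 0.0538 and 0.0525). None of these 4 passed on numbers 1 to 32 (H2-T23 0.75, Fezf2 -0.86, Hspa4l 0.49, Kcnq5 -0.67, adjusted p = 0.12 to 0.185) or with the eights fixed (0.0634 to 0.252), and H2-T23 did not in the authors' values (0.26, 0.0674) or without background correction (0.25, 0.0687). Hoxc6, undetected in wild-type mice, was at least 2.84-fold higher (fitted 2.37), the 1 of 7 homeobox genes that passed (1 over the list alone), while the list's median was -0.10, or 0 with undetected members at their bounds, its mean 0.30, and camera's adjusted p 0.331. Of the direct pathway genes only Drd1 (1 of 8, 1 over the list alone) passed, of immediate early genes only Homer1 (1 of 22, 1), and of cholesterol genes 4 of 18 fell (4, Msmo1 -0.60 and Srebf2 -0.57), with camera adjusted p of 0.058, 0.0884 and 0.058.

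Camera called the other lists named for 7 months, from projection neurons (adjusted p = 9.67e-23) to interneurons (0.00348). With an estimated correlation the call was lost for microglia (adjusted p = 0.0511 with an estimated correlation), chaperones (adjusted p = 0.0846 with an estimated correlation) and cortical excitatory neurons (adjusted p = 0.0759 with an estimated correlation). Medians with the eights fixed, the sets fixed and numbers 1 to 32 alone were -0.51, -0.52 and -0.56 for projection neurons, -0.58, -0.47 and -0.62 for the indirect pathway (all arrays -0.39), -0.29, -0.27 and -0.28 for glutamate receptors (-0.34), -0.30, -0.29 and -0.34 for potassium channels (-0.26) and -0.27, -0.27 and -0.33 for calcium and cAMP signalling (-0.27). They were -0.31, -0.22 and -0.40 for interneurons (-0.26), -0.30, -0.30 and -0.34 for cortical excitatory neurons (-0.37), 0.68, 0.64 and 0.77 for reactive astrocytes (0.60), 0.38, 0.37 and 0.44 for microglia (0.45), 0.43, 0.45 and 0.41 for interferon response (0.43) and 0.24, 0.26 and 0.34 for chaperones (0.27). Without background correction they shrank to -0.22 for the indirect pathway, -0.18 for calcium and cAMP signalling, 0.38 for reactive astrocytes and 0.18 for interferon response. Limma called 1411 genes, 593 higher and 818 lower (42.0% higher). Counts were 1081 with the eights fixed, 1211 with the sets fixed and 916 on numbers 1 to 32. Scale normalization called 708, of which 31.5% were higher, and left 19 projection neuron genes lower, with 7 reactive astrocyte, 8 microglia, 2 interferon and 2 chaperone genes higher. Without BACHD-ΔN17 mouse 3 the count was 859, and 14 of the 54 called genes taken first by size lost their call without some mouse.

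At 2 months limma called 1 gene in striatum and 548 at an unadjusted p under 0.05, where 561 were expected by chance. Pkp2, a desmosome protein, fell by 1.23 (SE 0.18, adjusted p = 0.00279, 6.98 ± 0.47 against 8.22 ± 0.17, n = 4 each). It did not pass on numbers 1 to 32 (-0.96, adjusted p = 0.27), without the dim arrays (-1.24, 0.12) or with its other probes (-0.26, 0.998, and -1.05, 0.368). The named genes with the next smallest p had log2 differences of 0.89 for Wt1, -0.75 for Rpn1, a subunit that adds sugars to proteins, and 0.52 for Onecut2, a transcription factor, all at an adjusted p of 0.597. Wt1 was undetected in wild-type mice and Rpn1 in BACHD-ΔN17 mice, with bounds of at least 1.03-fold and 1.39-fold. Pde10a gave -0.42 (adjusted p = 0.913), Drd2 -0.31, Drd1 -0.15, Cnr1 -0.46, Rgs4 -0.17, Ppp1r1b -0.09 and Scn4b -0.20 (all 0.99), and Gfap 0.08 and Bdnf -0.05 (both 0.999). Of the 31 projection neuron genes 0 passed (1 lower over the list alone), with a median of -0.08, or -0.09, -0.09 and -0.11 with the eights fixed, the sets fixed and numbers 1 to 32. Camera's call of this list (adjusted p = 0.0491) was lost (adjusted p = 0.602 with an estimated correlation), as were those of the calcium and cAMP list (0.0491, median -0.07, adjusted p = 0.389 with an estimated correlation) and the choroid plexus list (0.0491, median -0.30, adjusted p = 0.602 with an estimated correlation). Their medians with the eights fixed, the sets fixed and numbers 1 to 32 were -0.05, -0.07 and -0.12, and -0.23, -0.27 and -0.02 (choroid plexus -0.12 without background correction).

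Averaged over the 3 ages, with 12 mice per genotype, 27 of 31 projection neuron genes were lower in BACHD-ΔN17 striatum (28 over the list alone, median -0.49, or -0.49, -0.48 and -0.50 with the eights fixed, the sets fixed and numbers 1 to 32), and limma called 2454 genes, 1134 higher and 1320 lower. Counts were 2330 with the eights fixed, 2471 with the sets fixed and 1957 on numbers 1 to 32, and scale normalization called 1730 with 21.9% higher in place of 46.2%. The genotype difference itself changed between 2 and 11 months for 748 genes, 268 upwards and 480 downwards. It grew upwards for Plin4 (4.28), Nrn1 (3.27) and Ch25h (3.23) and downwards for Cyp2a5 (-3.31), Ccno (-3.02) and Ryr1 (-2.85). Plin4 did not pass with the eights fixed (3.06, adjusted p = 0.0958). Of 31 projection neuron genes 22 changed downwards (27 over the list alone, median -0.81, camera adjusted p = 1.24e-28), and of 36 calcium and cAMP genes 11 (17, median -0.32). Of 15 reactive astrocyte genes 6 changed upwards (10, median 0.78), and of 16 interferon genes 2 (6, median 0.53). These 4 calls of camera held with an estimated correlation. The medians with the eights fixed and on numbers 1 to 32 were -0.79 and -0.77 for projection neurons, -0.41 and -0.34 for calcium and cAMP signalling, 0.63 and 0.71 for reactive astrocytes and 0.81 and 0.55 for interferon response. Without background correction reactive astrocytes had 0.30 and interferon response 0.22, and under scale normalization calcium and cAMP signalling had -0.69. Counts for this change were 395 with the eights fixed and 484 on numbers 1 to 32, and scale normalization called 605 with 14.7% upwards in place of 35.8% and the median of all genes at -0.195. Differences at 7 and 11 months, which share no arrays, correlated across genes with r = 0.701 (genes are not independent replicates). Of the called genes 341 were higher at both ages where independent lists would share 51.8, 635 were lower at both (83 expected), and 0 were opposite.

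In cortex at 11 months, the 5 largest increases were those of transcription factors undetected in wild-type mice. En2, of midbrain and hindbrain development, stood at 10.67 ± 0.28 (normalized log2, n = 4), at least 25.3-fold higher (fitted 5.14, SE 0.20). Pou4f1, a sensory neuron factor, was at least 11.1-fold higher (4.58, SE 0.18), Barx1, of jaw and stomach development, at least 10.0-fold (4.47, SE 0.19), Hoxc6 at least 8.62-fold (4.20, SE 0.22) and Twist1, of mesoderm, at least 14.3-fold (4.18, SE 0.26). Shox2, a limb and heart factor detected in 1 wild-type mouse, rose by 3.72 (SE 0.28). Of 11 homeobox cluster genes 8 rose and 0 fell (8 over the list alone), among them Hoxb5 (3.42, SE 0.24, detected in 1 wild-type mouse). The list's median was 1.56, or 0.92 with undetected members at their bounds (8 were undetected in all wild-type mice). Camera's adjusted p was 2.25e-12, the call held with an estimated correlation, and the fitted median was 1.66 with the eights fixed, 1.58 with the sets fixed, 1.37 on numbers 1 to 32 and 2.01 on numbers 33 to 48, where 1 BACHD-ΔN17 mouse was measured. Without background correction it was 0.49, with 0.52 in the authors' values.

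**Figure D3:**
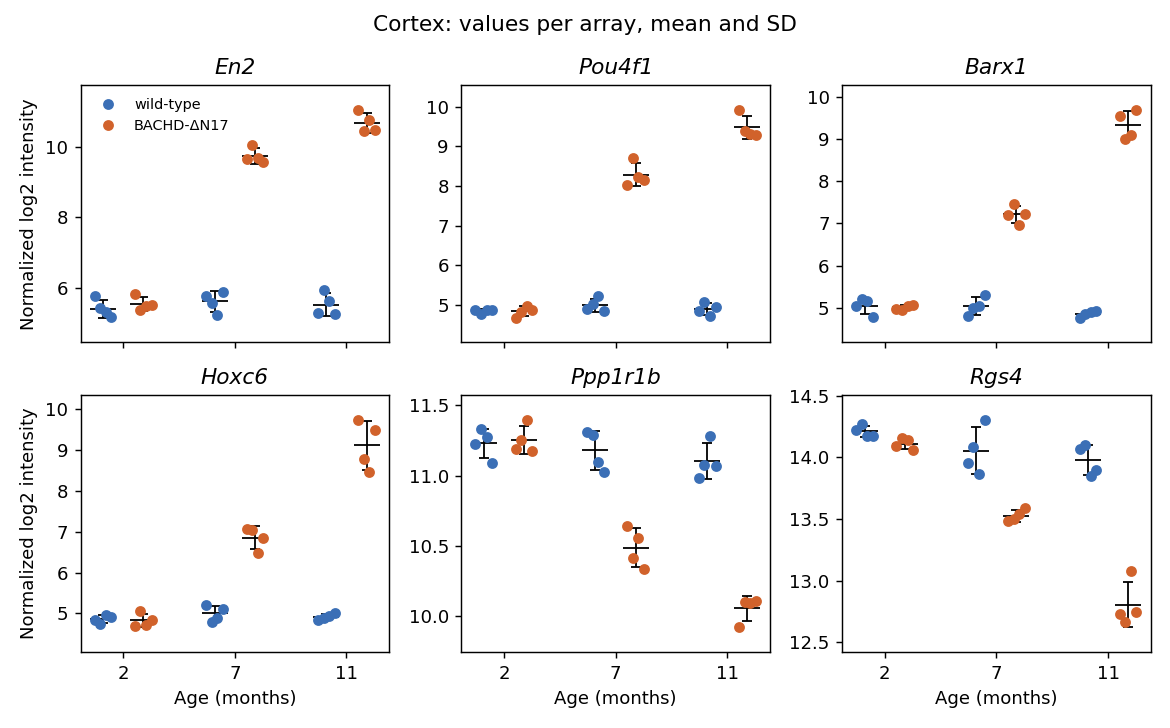
Normalized log2 intensity (y axis, scaled per gene) of 6 cortical genes by age in months (x axis), 1 point per mouse with the mean and SD of 4 mice. At 11 months En2 lay at 10.44 to 11.04 in BACHD-ΔN17 and 5.28 to 5.94 in wild-type mice, where it was not detected, and Rgs4 at 12.67 to 13.07 and 13.85 to 14.10.

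Neuronal signalling genes were lower in the same cortices at 11 months. Slc23a3, of a nucleobase and vitamin transporter family, had the largest decrease (-3.22, SE 0.28), with Egr2 (-2.61, SE 0.47), Ddit4l (-2.24), Sytl1 (-2.18), a vesicle protein, Otof (at least 2.84-fold, fitted -2.14), a calcium sensor of exocytosis, and Fst (at least 2.18-fold, fitted -1.94), an activin antagonist. The last pair were undetected in BACHD-ΔN17 mice. The opioid peptide precursor Pdyn fell by 1.45 (SE 0.14), Rgs4 by 1.17 (SE 0.09) and Ppp1r1b by 1.05 (SE 0.09), although other probes of Ppp1r1b gave -0.37 and -0.34 (adjusted p = 0.377 and 0.318). The projection neuron list, written for striatum, had 12 of 27 lower and 0 higher (13 over the list alone, median -0.27). Lower members without higher ones were also found among indirect pathway (3 of 4, 3, Drd2 -0.91 and Gucy1a1 -0.76), interneuron (5 of 13, 5, Cort -0.98 and Npy -0.65), immediate early (11 of 22, 12, Npas4 -1.92), cholesterol (7 of 18, 10, Stard4 and Srebf2 both -0.67), glutamate receptor (9 of 22, 11, Dlgap1 -0.68 and Camk2a -0.63), potassium channel (10 of 29, 10, Kcnip3 -0.95 and Kcnv1 -0.79), calcium and cAMP (11 of 34, 17) and astrocyte genes (5 of 16, 7). In the calcium and cAMP list Camk1g, a kinase, fell by 1.13 (-0.44 and adjusted p = 0.38 with another probe) and Camk4, another, by 0.99. Cortical excitatory genes had 6 of 21 lower and 2 higher (8 and 2), with Cux2 (-0.72), a factor of upper layers, falling most and Ccn2 (0.81), a secreted matrix protein, rising most. Microglia genes had 2 of 21 lower and 0 higher (2), P2ry13 (-0.75) and Cx3cr1 (-0.73), both surface receptors. Reactive astrocyte genes had 6 of 14 higher (7), led by Vim (0.98), a filament protein, and Serping1 (0.97), a complement inhibitor, and interferon genes 2 of 15 (4), Oasl2 (0.83) and Ifi27 (0.34). GABA receptor genes had 1 of 7 lower, Gabrd (-1.19), and 1 higher, Gabrg1 (0.67; 1 and 1), with a camera adjusted p of 0.536. For direct pathway genes, 1 of 5 lower (1, Pdyn), it was 0.191. The astrocyte list fell through Plpp3 (-0.78), a lipid phosphatase, and Slc1a2 (-0.75), the glutamate transporter. Of 2 other probes of Slc1a2, 1 also fell (-0.70, adjusted p = 8.91e-06) and 1 gave -0.42 (0.465).

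Camera called these lists, apart from the GABA receptor and direct pathway lists, from 1.15e-05 (projection neuron, calcium and cAMP, and immediate early genes) to 0.0272 (cortical excitatory neurons). The call was lost for immediate early genes (adjusted p = 0.119 with an estimated correlation), cholesterol synthesis (adjusted p = 0.0584 with an estimated correlation), cortical excitatory neurons (adjusted p = 0.0925 with an estimated correlation), microglia (adjusted p = 0.226 with an estimated correlation), reactive astrocytes (adjusted p = 0.0862 with an estimated correlation) and interferon response (adjusted p = 0.232 with an estimated correlation). Medians with the eights fixed, the sets fixed, numbers 1 to 32 and numbers 33 to 48 (1 BACHD-ΔN17 mouse) were -0.27, -0.26, -0.28 and -0.26 for projection neurons, -0.73, -0.67, -0.78 and -0.52 for the indirect pathway (all arrays -0.64) and -0.30, -0.26, -0.40 and -0.31 for interneurons (-0.29). They were -0.53, -0.59, -0.73 and -0.52 for immediate early genes (-0.56) and -0.36, -0.39, -0.40 and -0.45 for cholesterol synthesis (-0.37). They were -0.31, -0.28, -0.30 and -0.32 for glutamate receptors (-0.31), -0.23, -0.23, -0.24 and -0.33 for potassium channels (-0.21), -0.22, -0.24, -0.25 and -0.28 for calcium and cAMP signalling (-0.25) and -0.31, -0.33, -0.32 and -0.27 for astrocytes (-0.31). For cortical excitatory neurons they were -0.27, -0.25, -0.16 and -0.37 (-0.28), for microglia -0.22, -0.20, -0.17 and -0.32 (-0.24), for reactive astrocytes 0.45, 0.48, 0.32 and 0.62 (0.43), and for interferon response 0.41, 0.37, 0.30 and 0.39 (0.36). Without background correction they shrank to -0.34 for the indirect pathway, -0.25 for cholesterol synthesis, -0.20 for glutamate receptors, -0.18 for cortical excitatory neurons, -0.15 for microglia, 0.26 for reactive astrocytes and 0.15 for interferon response.

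Limma called 1782 of 11047 genes in cortex at 11 months, 770 higher and 1012 lower (43.2% higher). Counts were 2144 with the eights fixed, 2234 with the sets fixed, 1276 on numbers 1 to 32, 357 on numbers 33 to 48 (1 BACHD-ΔN17 and 2 wild-type mice) and 703 without the 4 dim cortical arrays of this comparison (31.2% higher). Scale normalization called 710 (28.3% higher), with 8 homeobox and 4 reactive astrocyte genes higher and 8 projection neuron, 8 calcium and cAMP, 4 potassium channel and 3 glutamate receptor genes lower. Without the dim arrays Egr2 (-2.15, adjusted p = 0.0511), Vim (0.79, 0.129) and Cx3cr1 (-0.54, 0.133) did not pass. On numbers 33 to 48, with that 1 BACHD-ΔN17 mouse, neither Vim (1.18, 0.0879), Cx3cr1 (-0.69, 0.107), Plpp3 (-0.40, 0.14) nor Slc1a2 (-0.54, 0.0831) passed, nor did P2ry13 on numbers 1 to 32 (-0.45, 0.189). Of other list members named here, Drd2, Ccn2, Stard4, Serping1, Oasl2, Ifi27, Dlgap1, Gabrg1, Camk4 and Cort did not pass on numbers 33 to 48 (adjusted p = 0.0961 to 0.791, Camk4 -0.26) or without the dim arrays (0.0556 to 0.388). Drd2 (0.0816), Cort (0.106) and Dlgap1 (0.0664) did not on numbers 1 to 32, nor Serping1 with the eights fixed (0.0532), nor Dlgap1, Ifi27 and Gabrg1 under scale normalization (0.055, 0.414 and 0.0697). With other probes Cort (-0.65, 0.0643), Ifi27 (0.33, 0.0649) and Cux2 (-0.77, 0.051, and -0.18, 0.794) did not pass. Leaving out BACHD-ΔN17 mouse 1 or 3 or wild-type mouse 3 ended the call of Dlgap1 (-0.55, -0.58 and -0.57, up to 0.0876). The call of Oasl2 ended without BACHD-ΔN17 mouse 3 or wild-type mouse 1 (0.57, 0.122, and 0.74, 0.067) and that of Ifi27 without wild-type mouse 1 (0.27, 0.0554). Serping1 lost its call without BACHD-ΔN17 mouse 1, 3 or 4 or wild-type mouse 1, 2 or 4 (0.64 to 1.0, up to 0.167). Of the 63 called genes taken first by size, 10 lost their call without some mouse.

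At 7 months En2, Pou4f1, Barx1, Hoxc6 and Twist1 were also higher in cortex. En2, detected in 1 wild-type mouse, rose by 4.11 (SE 0.20), Twist1, detected in 2, by 2.88 (SE 0.26), and Shox2 by 1.55 (SE 0.28). Undetected in wild-type mice were Pou4f1 (at least 5.67-fold higher, fitted 3.28), Tal1, a blood lineage factor (at least 2.94-fold, 2.21), Barx1 (at least 2.71-fold, 2.17), Hoxc6 (at least 2.12-fold, 1.85) and Hoxb5 (at least 2.91-fold, 1.79). The largest decreases were those of Sytl1 (-1.98, SE 0.28), Gpr153, an orphan receptor (-1.86), Mslnl (-1.75), Slc23a3 (-1.69), 1700016K19Rik (at least 2.04-fold, fitted -1.49) and Fst (-1.47). Pdyn (-1.13, SE 0.14), Ppp1r1b (-0.69), Scn4b (-0.61) and Nptx2 (-1.09), an activity-dependent pentraxin, also fell. Another probe gave -0.21 (adjusted p = 0.868) for 1700016K19Rik, and other probes gave -0.09 and -0.62 (0.977 and 0.209) for Ppp1r1b. Scale normalization ended the call of Scn4b (-0.58, 0.081).

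Of the 11 homeobox genes 2 rose (2 over the list alone), Hoxc6 and Hoxb5. The median was 0.24, or 0.13 with undetected members at their bounds. Lower genes without higher ones were found in the projection neuron (5 of 27, 6 over the list alone, median -0.15), interneuron (2 of 13, 2, -0.22, Reln -0.47 and Npy -0.46), astrocyte (1 of 16, 1, -0.23, Slc1a2 -0.59), glutamate receptor (1 of 22, 1, -0.13, Camk2a -0.47), potassium channel (2 of 29, 6, -0.12, Kcnip3 -0.49 and Kcnv1 -0.45) and calcium and cAMP lists (3 of 34, 4, -0.10, Camkk2 -0.63). These 6 lists passed camera, from 1.12e-05 (astrocyte) to 0.00378 (calcium and cAMP), also with an estimated correlation. Homeobox genes passed (0.000152) but not with an estimated correlation (adjusted p = 0.106 with an estimated correlation), and so did cholesterol synthesis (2 of 18 lower, 3, median -0.18, Stard4 -0.60 and Msmo1 -0.37, 0.000261, adjusted p = 0.0881 with an estimated correlation), cortical excitatory (1 of 21 lower, 3, -0.18, 0.0142, adjusted p = 0.0839 with an estimated correlation) and immediate early genes (2 of 22 lower, 2, -0.21, Nptx2 and Bdnf -0.81, 0.0148, adjusted p = 0.448 with an estimated correlation). Medians with the eights fixed, the sets fixed, numbers 1 to 32 and numbers 33 to 48 were 0.22, 0.23, 0.39 and 0.23 for homeobox genes, -0.12, -0.11, -0.09 and -0.19 for projection neurons and -0.21, -0.25, -0.27 and -0.15 for interneurons. They were -0.27, -0.23, -0.21 and -0.35 for astrocytes, -0.20, -0.13, -0.16 and -0.14 for glutamate receptors, -0.17, -0.20, -0.19 and -0.13 for potassium channels and -0.10, -0.12, -0.06 and -0.16 for calcium and cAMP signalling. For cholesterol synthesis they were -0.17, -0.19, -0.19 and -0.15, for cortical excitatory genes -0.19, -0.19, -0.13 and -0.18, and for immediate early genes -0.13, -0.21, -0.19 and -0.33. Without background correction homeobox genes had 0.10 and cortical excitatory genes -0.10.

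Limma called 196 genes in cortex at 7 months, 55 higher and 141 lower. Counts were 181 with the eights fixed, 307 with the sets fixed, 71 on numbers 1 to 32, 16 on numbers 33 to 48 and 64 under scale normalization. The latter called 2 homeobox genes higher and 1 projection neuron, 1 direct pathway and 1 immediate early gene lower, and no other gene of the lists just named. On numbers 1 to 32, Slc23a3 (-1.51, adjusted p = 0.0605), Fst (-1.18, 0.106), Npy (-0.43, 0.093) and Nptx2 (-0.90, 0.183) did not pass. On numbers 33 to 48, with 1 BACHD-ΔN17 mouse, Tal1 (2.23, 0.057), Barx1 (2.06, 0.057), Hoxc6 (1.82, 0.0824), Sytl1 (-1.66, 0.0544), Gpr153 (-1.21, 0.189), Mslnl (-1.92, 0.143), Fst (-1.71, 0.123), 1700016K19Rik (fitted -1.53, 0.0801), Ppp1r1b (-0.72, 0.126), Nptx2 (-1.07, 0.174) and Scn4b (-0.70, 0.116) did not. Neither did Reln (0.288), Npy (0.293), Camk2a (0.318), Camkk2 (0.375) or Stard4 (0.661). Of 2 other probes of Slc1a2, 1 also fell (-0.50, 0.00239) and 1 did not pass (-0.59, 0.659). Under scale normalization Reln (-0.46, 0.415), Npy (-0.44, 0.561), Slc1a2 (-0.58, 0.128), Camk2a (-0.48, 0.609), Camkk2 (-0.63, 0.117) and Stard4 (-0.60, 0.0717) did not. For Bdnf, Msmo1, Kcnip3 and Kcnv1 adjusted p was 0.0836 to 0.102 with the eights fixed, 0.081 to 0.602 under scale normalization and 0.0972 to 0.62 within either set, and another probe of Bdnf gave -0.45 (0.73). Bdnf lost its call without BACHD-ΔN17 mouse 1 or 2 or wild-type mouse 1 or 3 (-0.62 to -0.76, 0.0698 to 0.109), and Msmo1 without BACHD-ΔN17 mouse 1 or 2 or wild-type mouse 3 or 4 (-0.32 to -0.37, 0.0735 to 0.127). Kcnip3 lost it without BACHD-ΔN17 mouse 1, 2 or 3 or wild-type mouse 3 or 4 (-0.42 to -0.49, 0.0542 to 0.124) and Kcnv1 without any mouse but wild-type mouse 4 (-0.41 to -0.47, 0.0531 to 0.135). Stard4 lost it without BACHD-ΔN17 mouse 3 (-0.51, 0.0564). Of the 30 called genes taken first by size, 6 lost their call without some mouse.

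At 2 months limma called 0 genes in cortex and 219 at an unadjusted p under 0.05, with 552 expected by chance. The smallest p-values belonged to Abcc5, an efflux transporter (0.32), Niban2 (-0.47), Rasa1, a Ras regulator (-0.34), 2610524H06Rik (0.63) and Pdgfb, a growth factor (-0.63), all with an adjusted p of 1. Of 11 homeobox genes 0 passed (0 over the list alone), with a median of -0.09, and of 27 projection neuron genes 0 (0), with a median of -0.05. Camera's calls at this age, all below other genes, were lost: immediate early genes (0.0476, median -0.16, adjusted p = 0.627 with an estimated correlation), reactive astrocytes (0.0476, -0.19, adjusted p = 0.436 with an estimated correlation) and myelin genes (0.0487, -0.08, adjusted p = 0.627 with an estimated correlation). Their medians were -0.26, -0.30 and -0.05 on numbers 1 to 32 and -0.07, 0.00 and -0.10 on numbers 33 to 48, and -0.08 for reactive astrocytes without background correction.

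Over the 3 ages, 9 of 27 projection neuron genes were lower in BACHD-ΔN17 cortex (14 lower and 1 higher over the list alone, median -0.18) and 7 of 11 homeobox genes higher (8 over the list alone, median 0.56), with 12 mice per genotype. With the eights fixed, the sets fixed, numbers 1 to 32 and numbers 33 to 48 these medians were -0.15, -0.16, -0.11 and -0.21, and 0.62, 0.57, 0.53 and 0.75 (homeobox 0.19 without background correction). Limma called 1323 genes, 533 higher and 790 lower. Counts were 1308 with the eights fixed, 1755 with the sets fixed, 539 on numbers 1 to 32, 353 on numbers 33 to 48, and 477 under scale normalization with 27.3% higher in place of 40.3%. Between 2 and 11 months the genotype difference changed for 439 genes, 148 upwards and 291 downwards. En2 (5.01), Pou4f1 (4.59) and Barx1 (4.50) moved upwards, and Slc23a3 (-2.90), Ddit4l (-2.42) and Sytl1 (-2.22) downwards. Of 11 homeobox genes 7 changed upwards (8 over the list alone, median 1.70, camera adjusted p = 2.43e-16), of 27 projection neuron genes 7 downwards (9, median -0.19), of 34 calcium and cAMP genes 5 downwards (8, median -0.20), and of 14 reactive astrocyte genes 2 upwards (5, median 0.55). Camera called these 4 lists, also with an estimated correlation. The medians with the eights fixed and on numbers 1 to 32 and 33 to 48 were 1.75, 1.69 and 1.99 for homeobox genes, -0.20, -0.21 and -0.24 for projection neurons, -0.20, -0.26 and -0.27 for calcium and cAMP signalling and 0.52, 0.58 and 0.73 for reactive astrocytes. Without background correction homeobox genes had 0.56 and reactive astrocytes 0.26, and under scale normalization projection neurons had -0.32 and calcium and cAMP signalling -0.38. Counts for this change were 681 with the eights fixed, 704 with the sets fixed, 80 on numbers 1 to 32, 110 on numbers 33 to 48, 246 without the dim arrays and 119 under scale normalization. Differences at 7 and 11 months correlated across genes with r = 0.613, with 52 genes higher at both ages (3.83 expected of independent lists), 131 lower at both (12.9 expected) and 0 opposite.

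The genotype difference was compared between regions within mice. At 11 months it was more positive in striatum for Nrn1 (4.09), Lyzl4, a lysozyme-like gene (3.13), and Lyz2 (3.06), and more positive in cortex for Pou4f1 (-4.29), En2 (-4.02) and Barx1 (-4.00), as log2 differences of striatum minus cortex. Averaged over ages, Lyz2 (2.46), Nrn1 (2.35) and Gfap (2.16) lay on the striatal side and Pou4f1 (-2.36), En2 (-2.35) and Barx1 (-2.11) on the cortical side. Limma called 692 genes at 11 months, 332 on the striatal and 360 on the cortical side, and 636 over the ages (308 and 328). At 11 months 373 were called with the eights fixed and 93 without the dim arrays, where Nrn1 did not pass (3.16, adjusted p = 0.07). Over the ages 233 were called without the dim arrays. Scale normalization called 414 (24.9% striatal in place of 48.0%, median of all genes -0.153) and 365 (33.7% in place of 48.4%). Across genes, the 11-month differences of the regions correlated with r = 0.461. The regions share mice, 280 genes were higher in both (67.4 expected of independent lists), 412 lower in both (98.6) and 34 opposite.

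**Figure D4:**
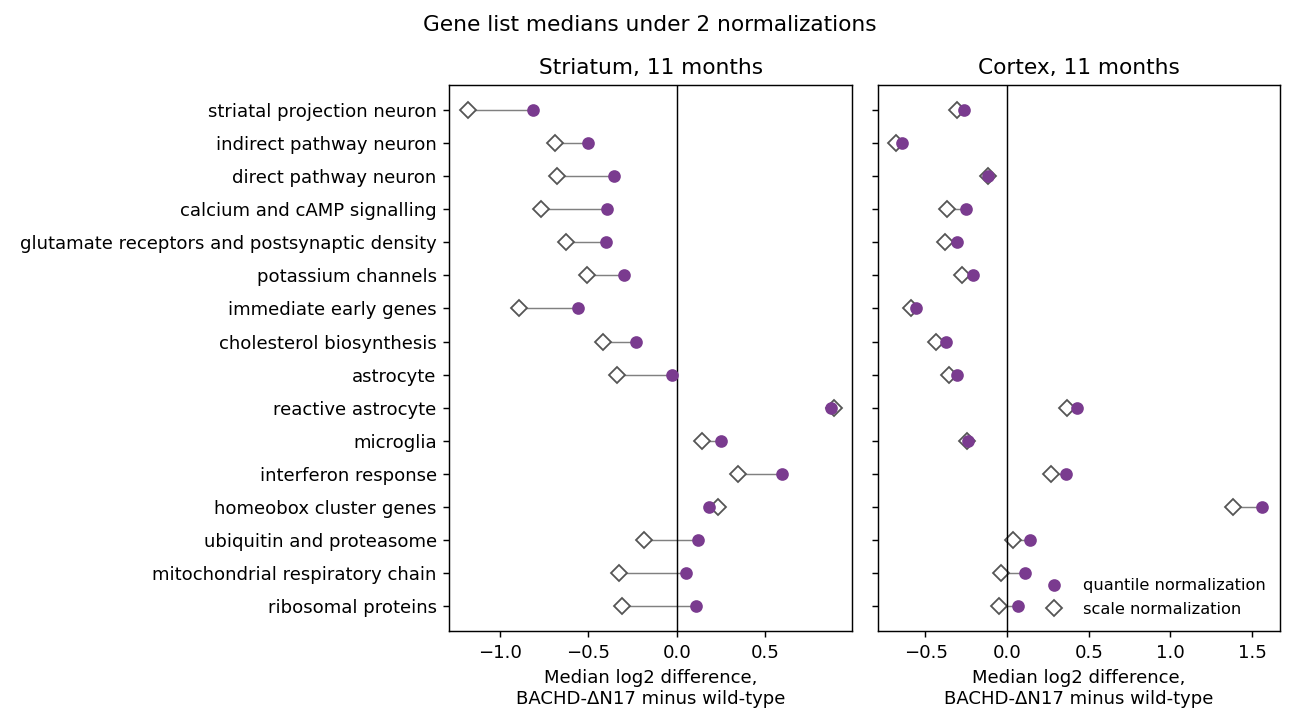
Median log2 difference at 11 months, BACHD-ΔN17 minus wild-type (x axis), of 16 gene lists (y axis) in striatum (left) and cortex (right), under quantile normalization (filled circles) and scale normalization (open diamonds). The mitochondrial medians turned from 0.05 to -0.33 in striatum and from 0.11 to -0.04 in cortex.

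For age in wild-type mice, 11 against 2 months, limma called 15 genes in striatum and 2 in cortex, and 1055 and 903 had an unadjusted p under 0.05 (561 and 552 expected by chance). In striatum Abca8a, a lipid transporter (1.32), and Sec14l3, a lipid binding protein (1.26), rose, Gpx8, a peroxidase of the endoplasmic reticulum (-1.23), and Gpr17 (-1.02), a receptor of oligodendrocyte precursors, fell, and Irak3 (1.38), a brake on innate immune signalling, and Bmp4 (-1.34), a secreted growth factor, passed with all mice. Irak3 lost its call without any of the 4 wild-type mice of 11 months (adjusted p = 0.0598 to 0.098) or without 2-month mouse 1 (1.01, 0.152), and Bmp4 without 11-month mouse 1 or 2 or 2-month mouse 1 (-1.31 to -1.35, up to 0.0647). With the eights fixed Sec14l3 (1.11, adjusted p = 0.092) and Irak3 (1.44, 0.0689) did not pass, nor on numbers 1 to 32 Gpr17 (-1.04, 0.0551) and Bmp4 (-1.37, 0.0966). Of the 15 genes 10 were higher and 5 lower (66.7% higher, 80% under scale normalization). Counts were 29 with the sets fixed and 9 on numbers 1 to 32. Of 8 oligodendrocyte precursor genes 2 fell (4 over the list alone, median -0.41, camera adjusted p = 4.86e-05, also with an estimated correlation), and of 22 myelin genes 0 (5, -0.20, 0.000288, adjusted p = 0.576 with an estimated correlation). With the eights fixed, the sets fixed and numbers 1 to 32 these medians were -0.49, -0.46 and -0.43, and -0.24, -0.22 and -0.17. The median of precursor genes was -0.15 without background correction. In cortex Casp1, the inflammasome protease, rose by 0.98, and Cldn11, a myelin tight junction gene, fell by 0.77. Casp1 lost its call without 11-month mouse 3 (0.93, adjusted p = 0.071) or 2-month mouse 2 or 3 (0.95, 0.0811, and 0.91, 0.0868), and under scale normalization, without the dim arrays and on numbers 1 to 32 (adjusted p = 0.0941, 0.0861 and 0.118). Cldn11 lost it on numbers 1 to 32 (-0.70, 0.0947). The cortical count was 20 with the sets fixed, 0 on numbers 1 to 32 and 8 on numbers 33 to 48. Of 22 myelin genes in cortex 1 fell (8 over the list alone, -0.25, 6.47e-07, adjusted p = 0.325 with an estimated correlation), with medians of -0.18 with the eights fixed, -0.38 on numbers 1 to 32 and -0.11 on numbers 33 to 48. Scale normalization moved the median of all genes to -0.119 in this comparison.

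Striatum and cortex of the 12 wild-type mice differed in 6394 of 11573 genes, 3301 higher in striatum and 3093 lower. Rgs9, a striatal regulator of dopamine receptor signalling (6.87), Isl1, a transcription factor of striatal neurons (6.64), and Ido1, a tryptophan enzyme (6.59), were highest on the striatal side, and Vip, a peptide of cortical interneurons (-5.80), Ntn5, a netrin (-5.42), and Slc17a7, the vesicular glutamate transporter (-5.39), on the cortical side. Of 31 projection neuron genes 29 were higher in striatum and 0 lower (29 over the list alone, median 2.29), and of 22 cortical excitatory genes 18 were lower and 3 higher (18 and 3, median -1.58). Fitted with the eights, these medians were 2.30 and -1.59.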

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

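The tests of the 3 patterns weighed here were chosen after the results were seen, and the counts over other splits of the mice were planned before. Among 526 groups of 4 mice, taken for the genes named here and in the other parts, 28 held a mouse that stood apart from the other 3 in normalized log2 intensity by Dixon's test, where chance gives about 1 in 20. In striatum at 2 months these were Pkp2 in BACHD-ΔN17 mouse 2 (7.68, the others 6.68 to 6.85), Htt in BACHD-ΔN17 mouse 1 (8.03, others 7.05 to 7.19) and Bdnf in wild-type mouse 4 (6.9, others 5.69 to 5.89). At 7 months they were Gfap in wild-type mouse 1 (8.27, others 7.28 to 7.4), H2-T23 in wild-type mouse 2 (5.93, others 5.22 to 5.33), Msmo1 in BACHD-ΔN17 mouse 3 (10.94, others 11.24 to 11.27) and Kcnj4 in BACHD-ΔN17 mouse 2 (11.39, others 10.91 to 10.92). At 11 months Slc35d3 stood apart in wild-type mouse 4 (9.43, others 10.23 to 10.36) and in BACHD-ΔN17 mouse 4 (9.62, others 9.21 to 9.26), Hap1 in wild-type mouse 3 (12.2, others 12.61 to 12.64), Upb1 in BACHD-ΔN17 mouse 4 (5.87, others 5.04 to 5.16) and Hoxc6 in the same mouse (7.04, others 7.79 to 7.92). BACHD-ΔN17 mouse 2 stood apart in Npas4 (5.7, others 6.83 to 7.01) and Ahsa2 (7.85, others 7.54 to 7.58), and BACHD-ΔN17 mouse 1 in H2-T23 (7.53, others 5.97 to 6.17) and Emcn (8.97, others 8.61 to 8.67).

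In cortex at 7 months Sostdc1 stood apart in BACHD-ΔN17 mouse 2 (6.14, others 6.35 to 6.39), and Hoxb5 (5.37, others 5.56 to 5.59) and Htt (7.46, others 7.13 to 7.16) in wild-type mouse 3. At 11 months Pdyn (10.71, others 10.26 to 10.31), Drd2 (6.1, others 5.48 to 5.55) and Npas4 (6.2, others 7.38 to 7.53) did in BACHD-ΔN17 mouse 4, and Pou4f1 (9.92, others 9.29 to 9.39) and Ppp1r1b (9.92, others 10.1 to 10.11) in BACHD-ΔN17 mouse 1. Hap1 did in BACHD-ΔN17 mouse 3 (12.14, others 11.89 to 11.92), Trp53inp1 in BACHD-ΔN17 mouse 2 (9.03, others 9.1 to 9.11), Camk2a in wild-type mouse 2 (13.71, others 14.08 to 14.12) and Uty in wild-type mouse 1 (6.48, others 7.09 to 7.16). No mouse had more than 3 of these in a region.

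The genotype difference itself differed between 2 and 11 months for 748 genes in striatum, most for Plin4 (4.28), Nrn1 (3.27), Ch25h (3.23), Cyp2a5 (-3.31), Ccno (-3.02) and Ryr1 (-2.85), and for 439 genes in cortex, most for En2 (5.01), Pou4f1 (4.59), Barx1 (4.5), Slc23a3 (-2.9), Ddit4l (-2.42) and Sytl1 (-2.22). It differed between regions at 11 months for 692 genes, most for Nrn1 (4.09), Lyzl4 (3.13), Lyz2 (3.06), Pou4f1 (-4.29), En2 (-4.02) and Barx1 (-4.0), and over the ages for 636, most for Lyz2 (2.46), Nrn1 (2.35), Gfap (2.16), Pou4f1 (-2.36), En2 (-2.35) and Barx1 (-2.11).

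Chance was excluded for the genotype difference in striatum at 7 months (1411 genes, highest other split 1) and 11 months (2119, highest other 407) and in cortex at 7 months (196, highest other 0) and 11 months (1782, highest other 36), where 1 of 35 splits of the 8 mice reached the real count. At 2 months the splits did not argue against it: 4 of 35 splits of striatum called at least 1 gene, and all 35 of cortex at least 0. The highest other split called 195 genes in striatum and 4 in cortex, and each put all arrays numbered 33 to 48 (3 and 4) in 1 group, which points to a structure of the samples. Of 100 splits, 1 reached the real mean over ages in striatum (2454, highest other 939) and in cortex (1323, highest other 627), which argues against chance there too. For the change between 2 and 11 months 4 of 100 splits called as many in striatum (748, highest other 1036) and cortex (439, 860). Both highest kept the genotypes of all 8 mice of 11 months, and so that age's difference, which leaves chance open. These counts were 395 and 681 with the eights of arrays as a fixed factor. Chance was excluded for the difference between regions at 11 months (692, highest other 93) and over the ages (636, 0). So it was for age in wild-type striatum (15, 1) and region in wild-type mice (6394, 5332, a split keeping 11 of 12 signs). Age in cortex (2, highest other 1) stays open, with 1 called without some mice.

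Projection neuron transcripts were lower in BACHD-ΔN17 striatum at 11 months. More cortical tissue is argued against by the 134 genes at least 4-fold higher in wild-type cortex (median 0.074, bootstrap SE 0.048). On numbers 1 to 32, all but 1 wild-type array, the list's median was -0.795 (SE 0.053), a weak test of array sets. The 16 members at least 4-fold higher in striatum had an SD 5.99 times their median SE (Ryr1 -3.15 to Gnal -0.62). Probes of 1 gene differed too (Ppp1r1b -0.67, -1.32 and -1.16), leaving an even loss of projection neurons open. An uneven loss or lower transcript levels in these neurons also stay open, with genotype or cohort as untested hypotheses.

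Homeobox cluster genes were higher in BACHD-ΔN17 cortex at 11 months. Hindbrain or spinal cord tissue in these samples is argued against by 21 abundant transcripts of those tissues, 4 of them also in other lists: their median difference was 0.087 (SE 0.067), 13 were undetected in both genotypes, 6 were detected on all arrays of each, and 1 of the 8 tested rose (Ddc, 1.10). That test replaced a first version, limited to the 8 tested members (median 0.186), and the test of sets one that also needed numbers 33 to 48, where 1 BACHD-ΔN17 mouse gave a median of 2.007, both after the results were seen. Background correction is argued against by 8 of 8 called members that also passed in the authors' values (list median 0.519 against 1.562). On numbers 1 to 32 the median was 1.366 (SE 0.5 over genes, 3 BACHD-ΔN17 and 2 wild-type mice). With the 2 wild-type but not all BACHD-ΔN17 arrays dim, this tests array sets weakly. Array brightness, cohort, or genotype raising these genes in cortical cells stay open as untested hypotheses.

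Microglia genes moved both ways in BACHD-ΔN17 striatum at 11 months. Lyz2 (3.62), Cd74 (1.82), Tyrobp (0.84), C1qa (0.77), Cst7 (0.76), C1qc (0.73), Fcgr3 (0.70), Trem2 (0.50) and C1qb (0.39) rose, while P2ry13 (-1.01), P2ry12 (-0.93), Gpr34 (-0.55), Aif1 (-0.49) and Cx3cr1 (-0.44) fell. More microglia of an unchanged kind as the whole cause is argued against by the 5 of 22 that fell. The blood list's median of 0.001 (SE 0.16, 5 genes) argues against more blood. On numbers 1 to 32, all but 1 wild-type array, 13 of 14 called members passed the same way, a weak test of array sets. Gpr34 (-0.49, adjusted p = 0.0997) did not pass. With the eights as a fixed factor 7 rose and 2 fell (P2ry12 and P2ry13), and under scale normalization 6 and 5, with C1qb (0.16, adjusted p = 0.535), C1qc (0.47, 0.07) and Trem2 (0.31, 0.177) not passing. A change of state of these cells, more cells of a changed kind, or other macrophages could each be involved, and genotype and cohort stay untested hypotheses.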

How the results depend on the processing

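The settings with the eights or sets of arrays as a fixed factor, with numbers 1 to 32 or 33 to 48 alone and without the 8 dim arrays were chosen after seeing the data, and the others before. Each count of called genes was recomputed under 16 to 21 alternatives. Of these counts 228 lay within 1.5 times the count reported and 57 did not, and no gene called in both had the opposite direction. Unless a clause says otherwise, the cause was not tested. Scale normalization gave 708 genes in striatum at 7 months, 64 and 710 in cortex at 7 and 11 months, 477 for the cortical mean over ages, 119 for its change from 2 to 11 months, and 414 and 365 for the difference between regions at 11 months and over the ages. In cortex age called 4 genes without background correction, 4 in the authors' values, 4 with the eights as a random block, 4 with array weights and 1 without a variance trend. With only the groups compared in the fit, and so fewer arrays, striatum at 2 months gave 0 (limma, 548 at an unadjusted p under 0.05 with all groups), cortex at 11 months 830 and age in striatum 8. The eights as a random block gave 679 for the change with age in cortex, and the name prefix as a random block 24 for age in striatum. Array weights gave 2480 in striatum at 7 months, 1333 for the change with age in striatum, 38 for age in striatum and 580 in cortex at 7 months. An adjusted p under 0.10 gave 779 for the change with age in cortex, 1163 for the regions at 11 months, and 27 and 16 for age in striatum and cortex, by construction. Adjusting the 6 genotype comparisons together gave 35 and 6 genes in striatum and cortex at 2 months and 317 in cortex at 7 months, because the many changes at later ages then set the threshold. The replicate block, which takes residual degrees of freedom, gave 1035 and 646 in striatum and cortex at 11 months and 207 and 78 for their changes with age. Replicate numbers did not pair the samples (mean residual correlation of samples with the same number 0.023 in striatum and -0.207 in cortex, 4 pairs each). With the eights as a fixed factor counts were 1389 in striatum at 11 months, 395 and 681 for the changes with age in striatum and cortex and 373 for the regions at 11 months, and with the sets as a fixed factor 307 in cortex at 7 months, 704 for its change with age, and 29 and 20 for age in striatum and cortex. Numbers 1 to 32, with fewer arrays, gave 916 in striatum at 7 months, 71 in cortex at 7 months, 539 for the cortical mean, 484 and 80 for the changes with age, and 9 and 0 for age in striatum and cortex (limma, 903 at an unadjusted p under 0.05 with all arrays). Numbers 33 to 48, with 1 BACHD-ΔN17 mouse at 7 and 1 at 11 months, gave 16, 357 and 353 in cortex at 7 months, at 11 months and over the ages, 110 for the change with age and 8 for age. Without the dim arrays striatum at 2 months gave 0, cortex at 11 months 703, its change with age 246, and the regions 93 and 233. With each mouse left out in turn counts were 1 to 1, 859 (without BACHD-ΔN17 mouse 3) to 1358 and 1587 to 2006 in striatum at 2, 7 and 11 months, 0 to 0, 134 to 178 and 1409 to 1674 in cortex, 2181 to 2747 and 1113 to 1381 for the means, 598 to 826 and 301 to 471 for the changes with age, 490 to 773 and 535 to 766 for the regions, 8 (without wild-type 2-month or 11-month mouse 1) to 20 and 1 (without 2-month or 11-month mouse 3) to 4 (without 2-month mouse 4 or 11-month mouse 1) for age and 6151 to 6349 for region in wild-type mice. Of 606 values of named genes, 599 kept their direction and side of the threshold in the authors' values, 599 without background correction, 579 with the sets as a fixed factor, 510 with the eights as a fixed factor, 490 without the dim arrays and 447 under scale normalization. On numbers 1 to 32, 436 kept both and 133 were weaker, with another probe 123 and 81 (8 reversed), and on numbers 33 to 48, 96 and 120 (2 reversed). Values reversed under scale normalization in striatum at 11 months for Fkbp4 (-0.037), Herpud1 (-0.05), Atp5g1 (-0.106), Ndufb6 (-0.206), Cox8a (-0.215), Ndufc2 (-0.177), Psmd7 (-0.006), Psmb7 (-0.086), Psma5 (-0.183), Psmc4 (-0.131), Rps6 (-0.083), Rpl39 (-0.149), Rps9 (-0.129), Rpl34 (-0.197) and Rps7 (-0.281). On numbers 33 to 48 they reversed in cortex at 11 months for Pvalb (0.013) and Ndufa10 (0.005). With another probe they reversed for Kcnc1 (0.009), Slc1a2 (0.195), Insig1 (0.083) and Dlgap2 (0.005) in striatum at 7 months, Ndufb6 (-0.158) in striatum at 11 months, Atp2b2 (0.204) in cortex at 7 months (the remaining probe of Slc1a2, Insig1, Dlgap2 and Atp2b2 passed the same way as the first), and Sqle (0.037) and Ndufb6 (-0.073) in cortex at 11 months, and none of the reversed values passed. Of 240 list tests camera called 99, of which an estimated correlation ended 47 and fry 10. Signal over background limits genes near the detection floor, whose differences are understated, and the dim arrays most.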

Other observations

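In this part the settings with the eights of arrays fixed, within sets and without the dim arrays were chosen after the data were seen, and the lists before. In striatum at 11 months, Cdkn1a, an inhibitor of the cell cycle, rose by 1.47 (SE 0.26), with 4 of 19 genes of the p53 and DNA damage list higher and 3 lower (4 and 3 over the list alone, camera adjusted p = 0.574). Of 22 myelin genes 2 rose and 5 fell (3 and 5), and 0 and 6 did under scale normalization, where the list's median turned from 0.08 to -0.28. Car2, a carbonic anhydrase (-0.95), and Ugt8a, an enzyme of myelin lipids (-0.58), fell most (camera adjusted p = 0.924). Bmp4 was the 1 of 8 precursor genes that rose (1.10, 1 over the list alone, camera adjusted p = 0.229). Of 13 endothelial genes 1 rose and 4 fell (2 and 4, camera adjusted p = 0.484), but with the eights fixed 1 fell, and Vwf (0.63) gave 0.42 (adjusted p = 0.173) and Emcn (-0.54) -0.19 (0.437). Ribosomal protein genes (10 of 41 higher, 11 over the list alone) and proteasome genes (6 of 29, 6) passed camera (adjusted p = 0.00182 and 0.00928; adjusted p = 0.0527 and 0.0156 with an estimated correlation), but their medians of 0.11 and 0.12 turned to -0.31 and -0.19 under scale normalization. Chaperone genes (6 of 22 higher, 6) did not pass (0.0618), and their median turned from 0.19 to -0.10. At 7 months the ribosomal (5 of 41 higher, 5), mitochondrial (5 of 66, 0) and proteasome lists (1 of 29, 1) passed camera (0.00377, 0.0355 and 0.029; adjusted p = 0.0709, 0.16 and 0.039 with an estimated correlation), and their medians of 0.10, 0.07 and 0.08 turned to -0.02, -0.08 and -0.06 under scale normalization.

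In cortex at 11 months Fas, a death receptor (1.55, SE 0.29), and Trp53inp1, a stress protein (0.69), rose, 2 of 19 p53 genes (2 over the list alone, 1 lower, camera adjusted p = 0.748). Neither passed on numbers 33 to 48 (1 BACHD-ΔN17 mouse, adjusted p = 0.181 and 0.199) or without the dim arrays (0.159 and 0.0821). Hspb8, a small heat shock protein, rose by 1.11 and Dnajb5 fell by 0.87, among 3 higher and 1 lower of 22 chaperone genes (4 and 1, camera adjusted p = 0.0135, adjusted p = 0.0804 with an estimated correlation), and neither passed without the dim arrays (0.127 and 0.0812). Of 29 proteasome genes 5 rose (5, camera adjusted p = 0.0154, adjusted p = 0.0527 with an estimated correlation). Myelin genes had 3 of 22 lower (3, camera adjusted p = 0.579), with Car2 (-0.73, -0.55 and 0.0913 on numbers 1 to 32) in front.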
